A study of Escherichia coli str. K-12 substr. MG1655 and Escherichia coli BW25113 with 11 samples.

How the data were processed

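Ribosome profiling and total mRNA sequencing were carried out on 11 Escherichia coli K-12 libraries. Per the labels' protocols, cells grown at 30 °C were collected by rapid filtration at an optical density of 0.6 and frozen. Polysomes were digested with micrococcal nuclease, and monosomes and disomes were separated on sucrose gradients. Total RNA was depleted of ribosomal RNA and fragmented by heat. Groups were taken from the titles and characteristics. The source field of the leucine-starved disome library names total mRNA, while its title and molecule subtype name disomes. It was treated as a disome library, since the series counts 7 ribosome profiling and 4 total mRNA samples.

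The deposited values are estimated counts per genome position and strand. In every library, isolated runs of under 5 reads summed to whole numbers within 0.05, so that each read had been spread evenly over the positions it kept and no depth scaling had been applied. A read covered a median of 8 to 38 positions, 8 in the serA total mRNA libraries and 13 to 14 in the leuB ones. The aligner, trimming and genome build are not given in the sources used here. Gene names and ends came from a RefSeq gene table of assembly ASM584v2, which names 4651 genes. That the files use its coordinates was checked on the data: the highest position in any file was 4641633, against a last gene end of 4641628 in the table, and in each of 10 blocks of the chromosome, in both rich monosome libraries, density fell 2 to 4 nt after the last base of genes. Whether positions are counted from 0 or 1 is open by 1 nt. Positions printed are those of the files, and windows are bounded from the gene ends in that table.

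The table gives no strand, so a gene's strand was the one with at least 90% of its reads over all libraries, with at least 20 reads. Of 4290 coding genes 3358 were used, after leaving out 885 with no strand and 47 that overlap a stable RNA gene. Reads were summed over each gene, and libraries were scaled to reads per 1000000 reads on these genes (RPM). The log2 ratio of 2 libraries used a prior of 1 read at the depth of the smaller library, for genes with at least 100 summed reads, with exact binomial (Clopper-Pearson) 95% intervals from the reads rounded to whole numbers. Where a library had 0 reads a floor of 3 counts in that library was used. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. No p-values were computed. Each comparison has 1 library per group. Intervals widen with fewer reads, and total mRNA, with the fewest coding reads, is the least precise kind.

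Translational efficiency was the footprint ratio over the mRNA ratio per gene. An interaction test within 1 strain has no residual spread, and a test of an effect common to both starvations, with strain as a block, was not run. Each of 29 gene lists was described by its median and by the percentile of that median among 10000 random lists of the same size matched on deciles of reads, for lists with at least 3 measured members, as a description of these libraries. Lists are called above or below the random lists where that percentile is over 97.5 or under 2.5. Random lists were drawn gene by gene, while members of 1 list can share an operon and so a transcript. Percentiles of such lists can therefore be too extreme. Named genes were the manipulated genes, the 6 highest and 6 lowest ratios in each comparison, and up to 4 members with the largest absolute ratio in each list described. Windows of 15 nt, codons 9 to 12 of leuL, tRNA reads and the genes named for them were chosen after the data were seen.

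Along genes, the first 20 and last 10 codons were left out, and genes needed at least 1 footprint per codon in both libraries. The density ratio of the 3′ and 5′ parts had 1 read added to each part. Start windows ran from −12 to 8 nt around the first base and stop windows from −15 to 5 nt around the last base, with relative density capped at 30. Medians and means over genes have percentile bootstrap 95% intervals from 1000 resamples of genes. Disome to monosome ratios compare a gene's shares of the coding reads of each library. They used 1140 genes with at least 50 reads in each of the 4 libraries.

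The planned codon occupancies, the tests by content of leucine or serine codons and the disome ratios per codon need a genome sequence and were not run. The gene lists, the rule for named genes and 29 alternatives, part of them at the codon level, were fixed before the data were examined. Alternatives covered scaling (including TMM factors from edgeR 4.0.16 in R 4.3.3), read minimums, gene ends, windows and caps. The steps were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

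The ratios were tested on simulated data with 200 genes changed 2-fold or 4-fold at the depths of 4 comparisons. All genes changed 4-fold were called at 2-fold in the mRNA comparison on leucine starvation (100% in a run on 1227 genes) and in the footprint comparison on serine starvation (100%, 2600 genes). Of unchanged genes 0 of 1055 were called in the former, and 1 of 918 in the mRNA comparison on serine starvation. The intervals held the true ratio for 95.1% of 1227 genes in the mRNA comparison on leucine starvation. A simulated log2 shift of −1 in the 3′ to 5′ ratio, made from the rich leuB monosome library, came back as a median of −1.00 in 764 genes. All simulated reads were independent Poisson draws around a set profile, which is what the intervals assume. The tests therefore check the calculation and leave out differences between libraries. They give no rate of false calls for the real libraries.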

Results

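The series measured ribosome-protected mRNA fragments (ribosome profiling) and fragments of total mRNA in Escherichia coli K-12 strains that cannot make leucine or serine. A strain with leuB disrupted, which lacks an enzyme of leucine synthesis, was grown in amino acid rich medium or starved of leucine for 30 min. A strain with serA disrupted, which lacks the first enzyme of serine synthesis, was grown rich or starved of serine for 30 min. A leuB strain that also lacks ssrA, the gene of the transfer-messenger RNA that releases stalled ribosomes, was starved of leucine. Monosome footprints come from single ribosomes, and disome footprints come from closely stacked pairs. There were 5 monosome, 2 disome and 4 total mRNA libraries, 1 per group, so no difference below has a replicate check. Intervals on ratios and shares of reads cover counting error only. Levels are given as RPM, reads per 1000000 reads on coding genes.

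Total reads ranged from 3970671 to 8821416 per library. Reads on coding genes ranged from 1735439 to 4296789 in the monosome libraries, from 195304 to 549090 in total mRNA, and were 1066485 (rich) and 7065004 (leucine-starved) in the disome libraries. Ribosomal RNA took 71.2% of the reads of the ssrA library and 15.3% of those of the rich serA monosome library, the highest and lowest shares among the monosome libraries. The deleted genes were as labelled: leuB had at most 14 reads in any leuB library against 5568 in the rich serA monosome library, serA had at most 18 reads in any serA library against 3225 in the rich leuB monosome library, and ssrA had 94 reads in the ssrA library against 80550 in the leuB leucine-starved monosome library.

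On leucine starvation the leucine operon stood highest among the biosynthetic groups, and genes of purine synthesis stood lowest. All 4 measured genes of the leucine biosynthesis list were at least 2-fold higher in mRNA (median log2 ratio 3.20, percentile 99.8 among random lists matched on expression) and in footprints (median 4.53, percentile 99.9). The list includes leuL, which encodes a leader peptide and not an enzyme. leuA, which encodes the first enzyme of the branch, had log2 ratios of 4.85 in mRNA (95% interval 4.40 to 5.43) and 5.33 in footprints (5.18 to 5.50), and the leader peptide gene leuL reached 6.71 in footprints (6.51 to 6.92). Of 13 purine genes measured in footprints 12 were at least 2-fold lower (median −3.92, percentile 0), with purL at −6.68 (−7.43 to −6.15) and guaB, which encodes an enzyme of guanine nucleotide synthesis, at −5.93 (−6.14 to −5.75).

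Other groups lay low on leucine starvation. All 9 genes of ATP synthase were at least 2-fold lower in mRNA (median −1.90, percentile 0.1), with atpA at −3.27 (−3.44 to −3.11). Of 14 tricarboxylic acid cycle genes 10 were at least 2-fold lower in footprints and none higher (median −1.49, percentile 0.27), with acnB, an aconitase, at −4.51 (−4.66 to −4.38). Pyrimidine genes had a footprint median of −3.40 (7 of 9 at least 2-fold lower, percentile 0.02), histidine genes −3.20 (8 of 9, percentile 0.01) and ribosomal proteins −1.10 (31 of 54, percentile 0.36). Among ribosomal proteins rpsA was lowest at −5.04 (−5.11 to −4.98), and the ribosomal protein median in mRNA was −0.40 (percentile 14.1). Flagella and chemotaxis genes had a footprint median of −2.62 (6 of 9, percentile 0.32). Threonine biosynthesis genes (−1.85), translation factors (−1.28), aminoacyl-tRNA synthetases (11 of 23 at least 2-fold lower) and ATP synthase genes (−2.46) also lay below the middle 95% of the random lists in footprints. In mRNA, purine biosynthesis (−3.34, all 6), the tricarboxylic acid cycle (−1.05, 7 of 14) and outer membrane proteins (−1.36, 4 of 7) did so too. Of 29 lists measured in footprints 3 lay above that range and 11 below, and of 22 in mRNA 6 lay above and 4 below. Major outer membrane proteins had a footprint median of −1.94, with ompC, a porin, at −3.95 (−3.99 to −3.91).

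Some stress lists lay high, while heat shock genes did not. The heat shock chaperone and protease list had a median of 0.07 in mRNA (4 of 13 at least 2-fold higher and 3 lower, percentile 38.9) and of −0.33 in footprints (4 of 14 higher and 5 lower, percentile 19.6). Phage shock genes had a footprint median of 1.95 (3 of 5 higher, percentile 87.1). Genes under the general stress sigma factor RpoS had a footprint median of 2.54 with 15 of 17 at least 2-fold higher (percentile 99.8), among them uspB at 5.93 (5.09 to 7.47) and osmC, a peroxidase, at 5.01 (4.65 to 5.43). Of 13 toxin-antitoxin genes 10 were at least 2-fold higher in footprints (median 2.29, percentile 98.8), with the antitoxin gene mqsA at 5.74 (5.39 to 6.17). In mRNA, 5 of 6 measured SOS response genes were at least 2-fold higher (median 2.17, percentile 98.9), with sulA, a cell division inhibitor, at 3.32 (2.62 to 4.31). Ribosome rescue and tmRNA partner genes had an mRNA median of 1.67 (6 of 8, percentile 98.6), with the RNase gene rnr at 2.68 (2.39 to 3.02). The branched-chain amino acid transport genes had an mRNA median of 2.42 (4 of 5, percentile 97.7) and the cysteine and sulfate assimilation genes 2.49 (3 of 5, percentile 98.8). In footprints these 4 lists lay within the middle 95% of the random lists: SOS response at 1.83 (7 of 11 higher, percentile 93.5), transport at 1.90 (4 of 6, percentile 89.3), cysteine and sulfate at 1.92 (7 of 9, percentile 93.1) and ribosome rescue at percentile 92.2 (5 of 8 higher and 2 lower).

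In mRNA only 3 of 31 listed RpoS genes were measured, with a median of 3.45. Also measured were 17 of 31 RpoS and 13 of 20 toxin-antitoxin genes in footprints, and 6 of 12 SOS genes in mRNA. The minimum of 100 summed reads passes a gene near 0 reads in 1 library only if it is high in the other. The measured members therefore need not stand for the whole list. With the prior of 1 read, the 6 highest mRNA ratios on leucine starvation belonged to puuC, pstS, cnu, phoH, phoB and fimB. pstS, which encodes a phosphate-binding protein, had 16030 RPM in the starved library against 160 in the rich one (log2 ratio 6.63, 6.31 to 7.00), and phoB, the response regulator of phosphate starvation, had a log2 ratio of 5.87 (5.19 to 6.89). puuC and cnu had 0 reads in the rich library, so with a floor of 3 counts they were at least 35.1-fold and at least 31.9-fold higher. These bounds lie below alaE at 5.32 and phoR at 5.17, so the ranks of puuC and cnu are open. The lowest were bioA, oppC, suhB, rnb, oppB and murE. oppC and oppB, which encode subunits of an oligopeptide transporter, had log2 ratios of −5.19 (−6.51 to −4.43) and −4.81 (−6.10 to −4.12). In footprints the 6 highest were yoaI, psiE, ybjM, ymiC, pstS and yohC, and the lowest were murF, purL, rnb, murE, suhB and secA. yoaI and yohC had 0 reads in the rich library and were at least 143-fold and at least 37.7-fold higher, so that the rank of yohC is open against phoB at 6.83. secA, the motor of protein export, was at −6.12 (−6.51 to −5.82), and pstS was at 7.13 (7.00 to 7.26).

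Of 1287 genes with at least 100 summed mRNA reads, 474 were at least 2-fold higher and 276 lower on leucine starvation. In footprints 1074 of 2415 genes were higher and 593 lower. The split depends on the scaling. With TMM factors the higher genes made up 51.2% of the mRNA calls instead of 63.2%, and with the median ratio set to 0 they made up 48.2% of the footprint calls instead of 64.4%. The median log2 ratio over all genes was 0.42 in mRNA and 0.67 in footprints, and the group medians above are to be read against it.

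On serine starvation most lists of amino acid synthesis lay low in footprints, as did both lists of nucleotide synthesis, and the RpoS list lay high. All 12 measured cysteine and sulfate assimilation genes were at least 2-fold lower in mRNA (median −3.58, percentile 0), as were 13 of 14 in footprints (median −3.23, percentile 0), with cysI, a sulfite reductase subunit, at −3.99 (−4.18 to −3.80) in footprints. Of 11 arginine biosynthesis genes 10 were lower in footprints (median −2.76, percentile 0.03), with carA at −4.03 (−4.22 to −3.85). All 9 methionine genes were lower (median −2.01, percentile 0.47), with metE at −3.70 (−3.75 to −3.64). The leucine biosynthesis list had a footprint median of −2.86 (3 of 4, percentile 0.95), and leuC was at −3.47 (−3.60 to −3.34). The branched-chain amino acid transport genes had a footprint median of −3.43 (6 of 7, percentile 0), with livJ at −3.91 (−4.01 to −3.82).

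Purine genes had a footprint median of −3.68 on serine starvation (12 of 13 at least 2-fold lower, percentile 0) and pyrimidine genes −3.87 (all 8, percentile 0), with pyrB, the catalytic subunit of aspartate transcarbamoylase, at −4.12 (−4.23 to −4.01). All 8 measured ATP synthase genes were lower (median −2.96, percentile 0.04), and 12 of 14 tricarboxylic acid cycle genes (median −2.29, percentile 0.41), with sucA at −3.68 (−3.80 to −3.56). Ribosomal proteins had a footprint median of −1.73, with 37 of 54 at least 2-fold lower and none higher (percentile 0.46). Histidine (−2.33), aromatic amino acid (−1.34) and flagella and chemotaxis genes (−2.11) lay below the middle 95% of the random lists as well. The isoleucine and valine list (−1.12, 6 of 11 lower and 2 higher, percentile 3.56) and the threonine list (−2.55, 3 of 4 lower, percentile 3.68) lay within it. In mRNA the lists below it were those of leucine (−2.76), branched-chain amino acid transport (−3.47), arginine (−3.04), cysteine, ribosomal proteins (−1.68), the tricarboxylic acid cycle (−2.56), ATP synthase (−3.27), purines (−3.68) and pyrimidines (−4.31). The mRNA medians of isoleucine and valine (−2.23), threonine (−2.60), aromatic amino acid (−1.08), methionine (−2.07) and serine and glycine genes (−2.10) lay within it. Of the serine and glycine metabolism genes in footprints, sdaA, a serine deaminase, was higher at 3.52 (3.31 to 3.75) and the glycine cleavage gene gcvT was lower at −3.39 (−3.73 to −3.09). The footprint median of that list was −1.75 (7 of 10 lower, 2 higher, percentile 0.49).

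RpoS genes had an mRNA median of 2.94 on serine starvation (16 of 19 at least 2-fold higher, percentile 100) and a footprint median of 1.89 (19 of 31 higher and 6 lower). bolA, a morphogene, had log2 ratios of 5.06 in mRNA (4.73 to 5.51) and 5.88 in footprints (5.79 to 5.99), and yjbJ had 6.10 in footprints (5.81 to 6.47). Of 15 toxin-antitoxin genes 14 were at least 2-fold higher in footprints (median 2.43, percentile 99.96), with mqsA at 5.59 (5.36 to 5.87). In mRNA only 3 of 20 listed genes passed the read minimum, all of them at least 2-fold higher (median 3.85). The 6 highest mRNA ratios belonged to alaE, yhhA, yohC, uspB, yodD and bolA. alaE, an alanine exporter, had a log2 ratio of 6.93 (6.07 to 9.92) from 314 reads against 3. The lowest were pyrB, purC, glnA, livJ, artJ and cysU, and glnA, which encodes glutamine synthetase, was at −4.92 (−5.86 to −4.28). In footprints the highest were ysdD, alaE, bssS, yjbJ, yddY and yjbT, and the lowest were pyrB, glnK, carA, pyrC, purL and cysI. ysdD had 0 reads in the rich library and was at least 43.2-fold higher, so its rank is open.

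On serine starvation 326 of 1131 genes were at least 2-fold higher and 362 lower in mRNA, and 984 of 2618 were higher and 608 lower in footprints. The mRNA balance turned with the read minimum, to 1013 higher and 667 lower with 1 read in each library. With the median ratio set to 0 the higher genes made up 49.5% of the footprint calls instead of 61.8%. The median log2 ratio over all genes was −0.02 in mRNA and 0.42 in footprints. With TMM factors the mRNA median over all genes was 0.05 on leucine starvation and −0.37 on serine starvation.

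**Figure D1:**
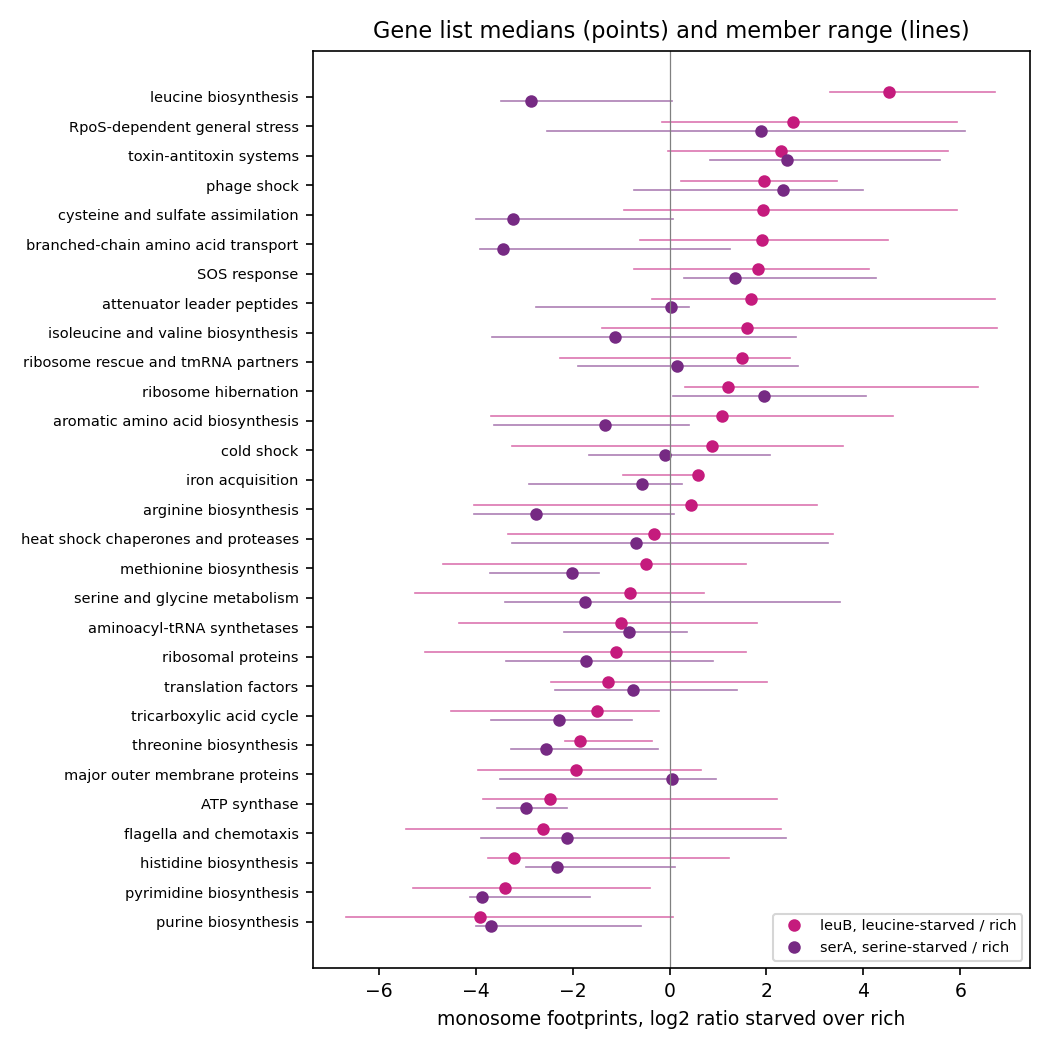
Median log2 ratio of monosome footprints, starved over rich, for each gene list with at least 3 measured members in both pairs (points), with lines from the lowest to the highest member. The leucine biosynthesis list lies at 4.53 on leucine starvation and −2.86 on serine starvation, while purine biosynthesis lies at −3.92 and −3.68.

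Both starvations shared much of their pattern across genes. Of 2286 genes with at least 100 summed footprint reads in each pair, 632 were at least 2-fold higher in footprints in both pairs, against 346.5 for independent lists, and 341 were lower in both, against 136. There were 49 genes higher on leucine starvation and lower on serine starvation, and 26 the reverse. Across genes the log2 ratios had a Pearson correlation of 0.677 in footprints and 0.609 in mRNA (920 genes). Genes are not independent replicates, and the 2 pairs share no library. The direction of these shared differences also rests on the rich libraries, which differed as follows.

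The 2 rich groups differed from each other, so that the pairs started from unlike levels. In the rich serA libraries, relative to the rich leuB libraries, 12 of 14 cysteine and sulfate assimilation genes were at least 2-fold higher in mRNA (median 6.88, percentile 100, or 6.78 with members at 0 reads set to their bound) and in footprints (median 7.02). cysD, an ATP sulfurylase subunit, had 1569 RPM in footprints against 1.25 (log2 ratio 9.97, 8.93 to 12.16). All 11 arginine biosynthesis genes (median 4.59 in mRNA, and the same with the member at 0 reads at its bound) and all 11 measured aromatic amino acid genes (2.71) were at least 2-fold higher, as were all 30 measured RpoS genes in footprints (4.57). Of 29 lists measured in footprints 13 lay above the middle 95% of the random lists and 3 below, and of 24 in mRNA 12 above and 2 below. Other lists above it in footprints were those of leucine (4.43), isoleucine and valine (2.98), threonine (2.82), aromatic amino acid (3.15) and methionine biosynthesis (2.14), branched-chain amino acid transport (3.43), attenuator leader peptides (2.13), ribosome hibernation (3.24), the tricarboxylic acid cycle (1.62) and purines (1.06). Cold shock genes (−1.59) and translation factors (−0.84) lay below it. Ribosomal proteins were lower (mRNA median −0.98, footprints −1.20, percentiles 0.03 and 0). cspA, a cold shock protein, was at −4.52 in mRNA (−5.10 to −4.08), and dtpA, a peptide transporter, was at −5.31 in footprints (−5.72 to −4.97). Of 2354 genes 671 were higher and 231 lower in footprints, and of 1164 genes 288 were higher and 79 lower in mRNA. The share of higher genes among the mRNA calls was 78.5%, and 45.5% with TMM factors. In footprints it was 74.4%, and 62.6% with the median ratio set to 0. Strain, medium and library batch cannot be separated in this pair.

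Footprint ratios followed mRNA ratios closely, with Pearson correlations across genes of 0.917 on leucine starvation (1276 genes) and 0.927 on serine starvation (1124 genes). Translational efficiency, the footprint ratio over the mRNA ratio, was at least 2-fold higher for 171 genes and lower for 181 on leucine starvation, and higher for 107 and lower for 66 on serine starvation. With the median ratio set to 0 the balance turned on leucine starvation, to 200 higher and 159 lower. Between the rich pairs it was higher for 40 and lower for 90 of 1151 genes. Aminoacyl-tRNA synthetase genes lay low in both pairs, with medians of −0.87 (9 of 22 at least 2-fold lower, percentile 0) and −0.46 (3 of 22, percentile 0.08). The phenylalanyl-tRNA synthetase gene pheT was at −2.35 and −3.35, and the seryl-tRNA synthetase gene serS was among the 6 lowest on leucine starvation. Tricarboxylic acid cycle (−0.78), purine (−1.13) and threonine biosynthesis genes (−0.92) lay low on leucine starvation as well. The leucine biosynthesis list lay high on leucine starvation (median 1.42, percentile 99.9), led by leuL at 3.15 and leuC at 1.98, with the lowest member at 0.48. leuL encodes a leader peptide, and its codons 9 to 12 held 69.7% of its footprints in the leucine-starved library. Its value therefore includes footprints gathered at that stretch. The highest on leucine starvation were ymiC, psiE, atpI, yhiY, leuL and yobF, and the lowest were tamB, truA, serS, fruK, rfbD and sspB. On serine starvation they were yobF, cvpA, secG, yceD, rimM and dusB, and rlmI, pheT, fhuA, zapA, dapE and galK. yobF was at 3.07 on leucine and 5.21 on serine starvation. Several of these rest on few mRNA reads, such as 9 for cvpA in the serine-starved library. Footprints were summed over whole genes, and the random lists were matched on reads and not on gene length. The fall of footprint density along starved genes, described below, was larger in longer genes. Whether the efficiencies of these genes and lists follow gene length was not tested.

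Footprints of starved cells lay nearer to the starts of genes than those of rich cells. In 178 genes of at least 310 codons, mean density relative to the gene was 2.83 at codons 20 to 40 in the leucine-starved library (95% bootstrap interval over genes 2.53 to 3.14) and 0.425 at codons 250 to 300 (0.368 to 0.489). In the serine-starved library it was 2.10 (1.89 to 2.35) and 0.543 (0.488 to 0.598). The rich libraries were nearly flat, from 1.10 to 0.946 in the leuB strain and from 1.09 to 0.948 in the serA strain. In total mRNA of the leucine-starved cells the same bins held 1.72 and 0.777 in 128 genes, and in the serine-starved cells 1.22 and 0.970, with a lower read minimum of 0.2 per codon chosen after the data were seen. In the rich total mRNA libraries they held 1.12 and 0.993 (leuB) and 1.11 and 0.998 (serA).

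**Figure D2:**
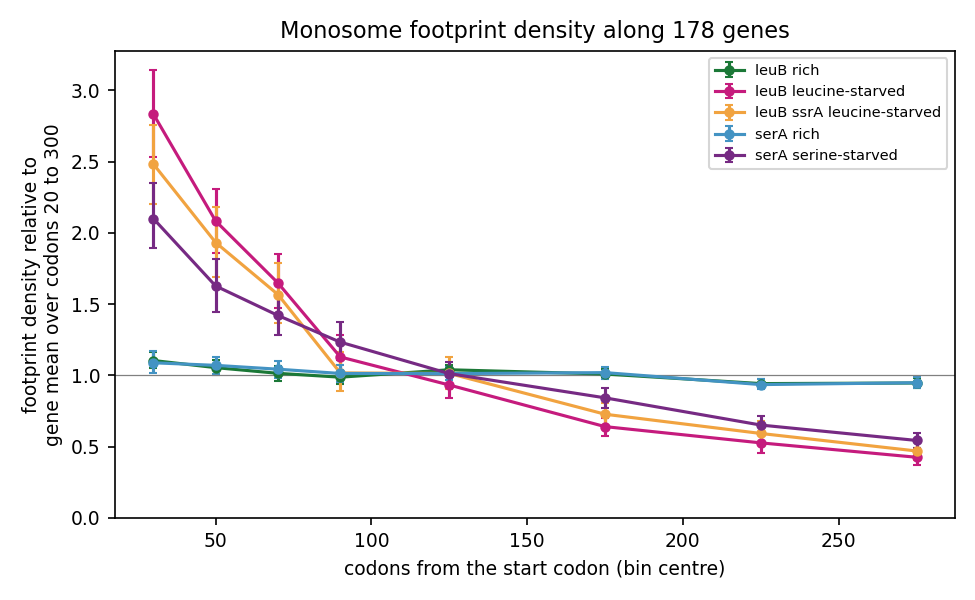
Mean monosome footprint density relative to the gene mean over codons 20 to 300 (y axis) by distance from the start codon in codons (x axis) in 178 genes, with 95% bootstrap intervals over genes as bars. The starved libraries start at 2.83, 2.48 and 2.10 and end at 0.425, 0.469 and 0.543, while both rich libraries stay near 1.

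The ratio of density in the 3′ part of the gene to that in the 5′ part, split at the midpoint, was lower by a median log2 value of −1.30 on leucine starvation (−1.43 to −1.17) and of −0.89 on serine starvation (−0.99 to −0.80). It was lower in 84.7% of 666 genes and in 81.8% of 819 genes. Between the 2 rich libraries the median was 0.04 (−0.00 to 0.08, 806 genes). The corresponding medians in total mRNA were −0.11 (153 genes) and 0.00 (73 genes). On leucine starvation the median was −0.82 in genes of 60 to 150 codons (133 genes) and −1.89 in genes of at least 500 codons (64 genes), and on serine starvation −0.43 (171 genes) and −1.25 (81 genes).

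Density at stop codons, relative to the gene mean, was lower in the starved monosome libraries. It averaged 0.71 of the gene mean on leucine starvation (0.616 to 0.814) against 1.87 in the rich library (1.76 to 1.99), and 0.975 on serine starvation (0.876 to 1.09) against 1.80 (1.68 to 1.91). Density already fell along genes when starved: at codons 250 to 300 of 178 genes it was 0.425 and 0.543, against 0.946 and 0.948 when rich. A lower stop codon density apart from that fall was not tested. At start codons the mean was 2.05 in the leucine-starved library (1.82 to 2.32) and 2.16 in the rich leuB library (2.06 to 2.28), while the median gene was lower when starved, at 0.906 (0.797 to 1.05) against 1.88 (1.75 to 2.01). The serine-starved library had a mean of 2.39 (2.16 to 2.63) against 1.03 in the rich serA library (0.954 to 1.12). The 2 rich libraries differed about as much from each other, at 1.05 in the serA strain (0.955 to 1.15) and 2.25 in the leuB strain (2.14 to 2.38), a log2 ratio of −1.10 (−1.20 to −1.02) beside 1.21 (1.08 to 1.34) for serine starvation, so the difference cannot be ascribed to starvation.

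Some short stretches held a large part of a gene's footprints in the starved cells. This comparison, and the genes named from it, were chosen after the data were seen. Of 3154 windows of 15 nt with at least 200 reads in the leucine-starved library, 343 in 246 genes held at least an 8-fold larger share of their gene than in the rich library. On serine starvation 70 of 1712 did, and between the 2 rich libraries 7 of 2878. In ubiE, which encodes a methyltransferase of quinone synthesis, positions 4018990 to 4019004 on the plus strand (codons 46 to 50) held 28.4% of the gene's footprints in the leucine-starved library (27.2 to 29.6%) against 0.251% in the rich one (3 reads, 0.0526 to 0.743%). In leuS, the leucyl-tRNA synthetase gene, positions 674649 to 674663 on the minus strand (codons 41 to 45) held 34.9% (33.6 to 36.2%) against 0.555% (0.363 to 0.789%). On serine starvation the highest ratio was in ftsK, a DNA translocase gene, at positions 933359 to 933373 on the plus strand (codons 46 to 50), with 16.7% (14.7 to 19%) against 0.686% (6 reads, 0.237 to 1.40%). Of the 343 windows 68.2% began within the first 50 codons, against 43.6% of all windows measured. Mean relative density at codons 20 to 40 was itself 2.83 when leucine-starved and 1.10 when rich, so an 8-fold larger share is easier to reach there. A placement near starts apart from that fall along genes was not tested. In the pair they were chosen in, the 343 windows held a median of 16.9% of their gene in the leucine-starved library and 1.04% in the rich leuB library. In the libraries not used for the choice they held 9.73% (leucine-starved ssrA), 3.44% (serine-starved) and 1.87% (rich serA). Which codons these stretches hold was not analysed here.

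The leader peptide gene leuL, whose translation controls the leucine operon, had a footprint level of 6792 RPM in the leucine-starved library against 64.8 in the rich leuB library. Codons 9 to 12, a stretch chosen after the data were seen, held 69.7% of its footprints in the leucine-starved library (69.2 to 70.3%) and 46.6% in the leucine-starved ssrA library (45.0 to 48.3%). They held 9.56% in the rich leuB library (6.03 to 14.6%, 206 reads), 8.07% in the serine-starved library (6.24 to 10.1%) and 30.4% in the rich serA library (27.5 to 33.4%).

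**Figure D3:**
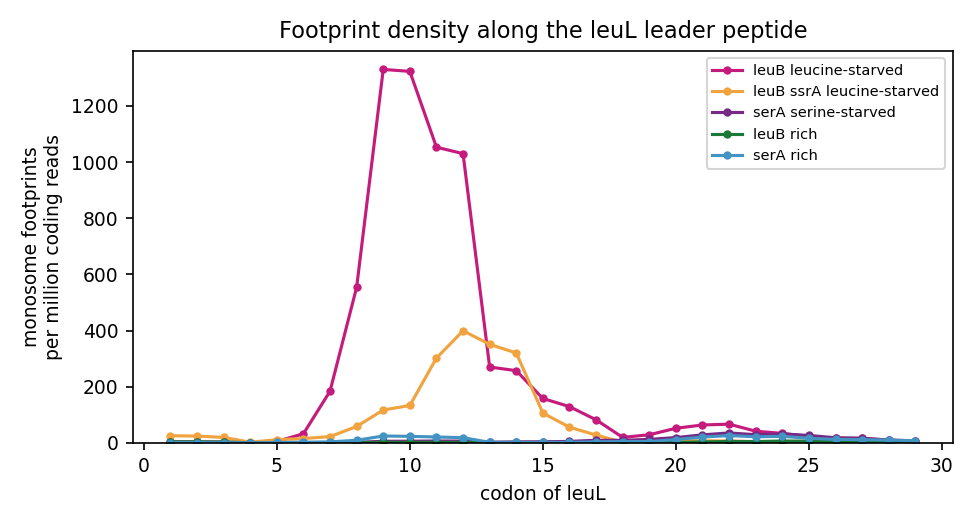
Monosome footprints in RPM (y axis) at each codon of leuL (x axis), 1 line per library, with no replicate and no error drawn. The leucine-starved library peaks at codons 9 and 10 with 1330 and 1323 RPM, and the leucine-starved ssrA library peaks at codon 12 with 399.

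Starved of leucine, cells lacking ssrA differed from the leuB strain in fewer genes than starved cells differed from rich ones. In footprints 124 of 2219 genes were at least 2-fold higher and 244 lower. The 6 highest were rclA, lysA, cysJ, rne, codB and tcyP, with rclA at 4.54 (3.97 to 5.73) and rne, which encodes RNase E, at 2.51 (2.34 to 2.70). The lowest were phoH, yoaI, yobF, ariR, puuC and bssS, with phoH at −3.16 (−3.45 to −2.89) and puuC at −2.59 (−2.97 to −2.25). Methionine biosynthesis genes had a median of 0.88 (4 of 9 at least 2-fold higher, percentile 99.97), cysteine and sulfate assimilation genes 0.69 (3 of 10, percentile 99.9) and aminoacyl-tRNA synthetases 0.48 (3 of 23, percentile 99.9). Of the 3 synthetase genes, pheT at 1.05 was at −0.34 and pheS at 1.08 was at 0.66 with the gene ends left out. Histidine biosynthesis genes had 0.69 (2 of 6) and iron acquisition genes −1.72 (2 of 3 lower). The leucine biosynthesis list had a median of −1.03 (percentile 0.33), with leuL at −1.74 (−1.79 to −1.69) and leuA at 0.99 (0.96 to 1.03). Density in the ssrA library was 2.48 at codons 20 to 40 and 0.469 at codons 250 to 300, and the 3′ to 5′ ratio was higher than in the leuB strain by a median of 0.18 (0.13 to 0.24, 751 genes). The shortest genes did not show this: the median was −0.04 (−0.19 to 0.14) in 168 genes of 60 to 150 codons. In 58 genes of at least 500 codons it was 0.29 (0.14 to 0.54). The median start codon density was 1.52 (1.42 to 1.73) against 0.814 (0.731 to 0.961), a smaller difference than between the 2 rich libraries, at 0.615 (0.563 to 0.692) and 1.89 (1.75 to 2.03).

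Disome footprints of leucine-starved cells were concentrated in a few genes and near gene starts. cspE, a cold shock family gene, had 492694 disome reads and pstS 480365, and the top 10 genes held 36.6% of the coding disome reads against 22.0% in the rich library. The highest ratios over the rich disome library were those of cspD, pstS, yoaI, phoH, mqsA and ychH, with pstS at 8.95 (8.72 to 9.20) and mqsA at 7.78 (6.97 to 8.91). yoaI and phoH had 0 rich disome reads and were at least 105-fold and at least 80.6-fold higher, bounds below ilvM at 7.01, so their ranks are open. The lowest were guaB, arnA, oppB, rho, prs and secA, with guaB at 64 reads against 5995. Of 1946 genes 657 were at least 2-fold higher and 783 lower, a balance that turned to 459 higher and 355 lower with at least 500 summed reads. All 13 purine biosynthesis genes (median −4.60, percentile 0) and all 14 tricarboxylic acid cycle genes (−3.12, percentile 0.04) were lower. Ribosomal proteins (−1.51), aminoacyl-tRNA synthetases (−2.33), translation factors (−2.15), pyrimidine (−5.76), histidine (−3.70), threonine (−3.80), serine and glycine (−2.81), ATP synthase (−3.34) and outer membrane protein genes (−2.90) also lay below the middle 95% of the random lists. RpoS (1.44) and cysteine and sulfate genes (2.59) lay above it. The 3′ to 5′ ratio of disomes was lower by a median of −2.36 (−2.65 to −2.04, 330 genes). Stop codon density relative to the gene mean was 0.297 (0.226 to 0.383) against 3.31 (2.89 to 3.72), a value not separated from the fall along genes.

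Disome reads relative to monosome reads ranked genes differently in the 2 conditions, with a Spearman correlation across 1140 genes of 0.188. The difference was lowest for leuL, with 98 disome and 206 monosome reads in rich cells and 188 and 29186 in starved cells, a log2 value of −8.50. yhcN, ivbL, the leader peptide gene of an acetolactate synthase operon, and mgtS followed at −7.02, −6.35 and −5.85. The chaperone gene dnaJ was highest at 2.46, followed by cspE at 2.31, queE at 2.26 and yfeX at 2.12.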

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

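The tests of a wrong label, of a single library, of strain and batch, of spread between libraries and of depth by thinning were chosen only after the results they bear on had been seen, while the capping of high positions and the subtraction of the mRNA change had been planned, the latter with the bounds that decide it set only after its values were seen.

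Some gene groups lay in opposite directions under the 2 starvations, and the difference was not tested, since each group has 1 library. The leucine biosynthesis list had an mRNA median log2 ratio of 3.20 on leucine and −2.76 on serine starvation, and a footprint median of 4.53 and −2.86. The mRNA medians were 2.42 and −3.47 for branched-chain amino acid transport and 2.49 and −3.58 for cysteine and sulfate assimilation. Of 7 listed transport genes, 5 were measured on leucine and 7 on serine starvation. Of 14 listed cysteine and sulfate genes, 5 and 12 were, so the medians of a list do not cover the same genes. The footprint medians were 1.90 and −3.43 for transport and 1.92 and −3.23 for cysteine and sulfate. On leucine starvation these had percentiles of 89.3 and 93.1, so neither list is called above the random lists in footprints. Outside the coding genes, serine tRNA genes took 4.81% of the tRNA reads in the serine-starved monosome library (4.77 to 4.85%) against 2.08% in the rich one (2.06 to 2.11%), a signal in reads that the comparisons of coding genes do not use. Their share was 4.43% and 3.79% in the leucine-starved and rich leuB libraries and 17.6% in the ssrA library. Other tRNA shares also differed on serine starvation, with threonine tRNA genes at 32.1% against 12.6% and leucine tRNA genes at 38.1% against 53.3%. In total mRNA the serine tRNA share was 9.58% when starved and 9.85% when rich. On leucine starvation the leucine tRNA share of monosome libraries was lower, at 47.2% (47.1 to 47.3%) against 54.3% (54.2 to 54.3%), and in total mRNA it was higher, at 11.1% against 9.38%. The genes did not move together: of the tRNA reads of the monosome libraries, 1049595 when starved and 1691894 when rich, leuT had 127604 and 555533, while leuZ had 186396 and 135949. The cause was not tested.

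The serine-starved ratios start from rich serA libraries in which these groups already lay far above the rich leuB libraries. A swap of the rich serA monosome library with a starved one is argued against by its 3′ to 5′ density ratio. Its median log2 value was −0.08 (−0.11 to −0.04), against −0.97 in the serine-starved library. This ratio sets starved cells apart from unstarved ones, so it cannot test a wrong label of the medium. An artifact of that 1 library is argued against by the separately made total mRNA libraries, where the cysteine and sulfate list had a median of 6.88 (6.78 with members at 0 reads set to their bound), with members from 0.42 to 9.16. Strain, medium and library batch cannot be told apart, because there are 2 strains with 1 rich library of each kind. A biological difference between the strains also stays open and untested.

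Footprint density was lower toward the ends of genes in both starved monosome libraries. Loss of the 3′ parts of mRNAs as the whole cause is argued against by subtracting the change in total mRNA of the same genes, which left medians of −0.93 on leucine starvation (−1.07 to −0.55, 149 genes, −0.99 before) and −0.71 on serine starvation (−0.97 to −0.46, 70 genes, −0.74 before). Capping each position at 10 times its gene mean left −1.26 (−1.34 to −1.12) and −0.86 (−0.94 to −0.78), so density above that cap does not give the fall. A monosome read covered a median of 12 to 15 positions, and a strong stretch of that length can stay under the cap. The capping therefore cannot decide whether a few such stretches in the 5′ part give the fall. The subtraction of the mRNA change covers only the better measured mRNAs. In 128 genes with a lower minimum the leucine-starved mRNA density itself ran from 1.72 to 0.777. A loss or slowing of ribosomes within genes is a hypothesis that these values leave open, and its link to leucine or serine codons was not tested.

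The 3′ to 5′ ratio was slightly higher in the ssrA library than in the leuB library, both starved of leucine. An effect of the lower coding depth of the ssrA library, through the read minimum or the added read, is argued against by thinning. With the leuB reads thinned to that depth the median was 0.19 (0.11 to 0.25) against 0.18. Thinning takes reads evenly from both parts of a gene, so a value near 0.18 was likely beforehand. It does not bear on other differences of the ssrA library, such as its ribosomal RNA share of 71.2%. The same measure between the 2 rich libraries was 0.04, but 1 pair of libraries gives no spread between libraries, so a chance difference between single libraries cannot be told apart from an effect of ssrA. With at least 3 footprints per codon the median was 0.11 (−0.00 to 0.21).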

How the results depend on the processing

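The thinned comparison with the ssrA library was chosen after seeing the data, and the other alternatives were planned. No group has a second library, so no library could be left out. No paired analysis was possible for either starvation alone because each group has 1 library. An effect common to both starvations could be fitted with strain as a block, with 1 residual degree of freedom, and was not. The planned codon-level alternatives were not run for lack of a sequence. Of the alternatives for list medians 209 stayed within 1 SD of the members and 6 did not, with none of opposite sign. For named genes the bound on a move was the distance from the counting interval's centre to its ends, with open ends set at a fixed distance. Of these alternatives 481 moved by no more than that and 190 moved further. The remaining one turned: pheT in the ssrA comparison, at 1.05, was −0.34 with the gene ends left out, and the cause was not tested.

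Counts of genes moved with the read minimum, which sets how many genes are tested. With at least 500 summed reads the higher and lower genes numbered 100 and 93 (mRNA, leucine), 47 and 118 (mRNA, serine), 669 and 356 (footprints, leucine), 564 and 400 (footprints, serine), and 60 and 121 (ssrA). For disomes they were 459 and 355, so that the higher genes outnumbered the lower ones, against 657 and 783 before. For translational efficiency they were 29 and 54 on leucine and 15 and 14 on serine starvation. With 1 read in each library they were 1065 and 598 (mRNA, leucine), 1013 and 667 (mRNA, serine), 259 and 379 (ssrA), and 694 and 1373 (disomes). The balance turned as well: the higher genes made up 28.5% of the mRNA calls on serine starvation with 500 reads, 47.4% with 100 and 60.3% with 1 read, and 56.4%, 45.6% and 33.6% of the disome calls. The cause of these shifts in balance was not tested.

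In the starvation, ssrA and disome comparisons the change in the 3′ to 5′ ratio kept its sign under each alternative run, but its size moved. With at least 3 footprints per codon it was −1.10 on leucine starvation, 0.11 for ssrA and −1.84 for disomes. Comparing the outermost parts of genes split into 3 gave −1.58 on leucine starvation, −1.21 on serine starvation and −2.81 for disomes. Subtracting the mRNA change gave −0.93 on leucine and −0.71 on serine starvation. In the same genes the values without it were −0.99 and −0.74, so most of those moves came with the smaller set of genes. Between the rich libraries it gave 0.12. The cause of this and of the moves under the other settings was not tested. In log2 ratios of mean density, the stricter minimum gave at start codons −0.29 (leucine, −0.08 before), 1.34 (serine) and −1.21 (rich pair), and at stop codons −1.01, −0.68, −0.33 (ssrA) and −2.99 (disomes). Narrower windows gave −0.25 (leucine) and −1.22 (rich pair) at start codons. The disome to monosome change had a median of −1.11, and −0.62 with the stricter minimum. It compares shares of each library's coding reads, so it does not give the change in the amount of disomes. The cause of the moves in start and stop densities and in this ratio was not tested.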

Other observations

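The gene lists and windows here were chosen after their values were seen. Phosphate starvation genes were higher in leucine-starved cells. Their list was written after pstS, phoB and phoH had appeared among the highest ratios, so its median is not independent evidence. All 11 measured members were at least 2-fold higher in mRNA (median log2 ratio 4.37, from 1.16 to 6.63), with the sensor kinase gene phoR at 5.17 (4.39 to 6.46). In footprints 10 of 12 were at least 2-fold higher (median 5.62), and the other two, phoU at −0.08 (−0.35 to 0.19) and pstA at 0.68 (0.35 to 1.01), were not. On serine starvation 10 of 14 were higher in footprints (median 2.24) and ugpC was lower at −1.42 (−2.04 to −0.92). In the rich serA library 4 of 10 already lay at least 2-fold above the rich leuB library in footprints, namely psiE (4.71), phoH (4.32), ugpC (2.28) and ugpB (2.06), so the pairs started from unlike levels. In the ssrA library 6 of 12 were at least 2-fold lower than in the leuB starved library (median −0.96), a comparison that shares that library with the leucine starvation ratios.

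Oligopeptide transport and cell wall precursor genes were at least 2-fold lower on leucine starvation in 10 of 11 cases in mRNA (median −4.12) and in all 13 in footprints (median −4.74). On serine starvation 7 of 9 were lower in mRNA (median −2.61), none of them an oligopeptide transport gene: oppA, the only such gene measured, was at 0.52 (0.25 to 0.78). In footprints 8 of 13 were lower (median −1.76). Of the transport genes oppD was among them at −1.43 (−1.75 to −1.14), while oppA was at 0.49, oppB at 0.01, oppC at −0.71 and oppF at −0.92. In the rich serA library oppB, oppC, oppD and oppF already lay below the rich leuB library, at −1.89, −2.52, −2.40 and −2.36, so the pairs started from unlike levels.

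Of 679 windows measured in both starved monosome libraries, 47 had an 8-fold larger share on leucine starvation and 19 on serine starvation, with 5 in common against 1.32 for independent lists. The lists are not independent. In each pair such windows were concentrated in the first 50 codons, with 68.2% and 72.9% there against 43.6% and 47.8% of all windows measured. This placement was not separated from the fall of density along starved genes. Whether that placement alone gives the overlap was not tested.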
